A study of Mus musculus with 30 samples.

How the data were processed

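Poly(A)-selected, stranded RNA libraries were sequenced as paired 150 bp reads, per the labels. The deposited table held whole-number read counts per gene for 30 libraries. Per the submitters' processing notes, Trim Galore 0.4.1, FastQC, STAR 2.6.0a and DESeq2 were used, with the mouse build GRCm38 (mm10). The read counter, its strand setting and its annotation release are not given in the sources used here. Reads of near-identical copies (Hspa1a and Hspa1b, Ifit3 and Ifit3b, the guanylate-binding protein genes, H2-T23, the haemoglobin genes) and of overlapping or antisense genes may therefore have been divided or dropped, and values of these genes are uncertain. Per the labels, a hippocampal library of the saline condition had been excluded for poor quality. It was not analysed here.

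The table listed 48820 versioned Ensembl gene identifiers, of which 48144 (98.6%) had a symbol in GENCODE M21 (83.2% with the same version), and 15948 had no counts. Coordinates are from that annotation on GRCm38, counted from 1. Entries without a gene name held at most 0.261% of a library. A ratio of pooled counts per pooled total, with its exact 95% interval, was computed for genes with at most 30 counts in the saline group. It is printed for some of these, including those with 1 to 3 saline counts, and the others carry fitted fold changes, and 3 counts over the saline group stand in where there were none. Intervals and floors cover counting error alone, since reads are not independent molecules. Replicate libraries differed by more than sampling noise (chi-square per gene 2.23 to 25.02 over pairs of a group, lowest Pearson r 0.9883), so none was counted as a duplicate.

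Libraries were grouped by tissue, treatment and time as the labels give them, in 8 groups. Totals of 16826882 to 33034295 counts per library set the precision, which is lowest for genes with few counts. Each tissue's 15 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and total of 15, TMM scaling, robust glmQLFit, glmQLFTest), so that the groups share an estimate of the spread. LPS groups were compared with saline (6 comparisons) and with LPS at 6 h. A fit of all 30 libraries gave the differences between tissues, as interactions, and the comparison of tissues in saline, 14 comparisons in all. Genes tested were 17289, 17111 and 17650, with a common biological coefficient of variation of 0.069, 0.103 and 0.088 and TMM factors of 0.971 to 1.018, 0.931 to 1.038 and 0.956 to 1.052 (hippocampus, cortex, both). Adjusted p values are two-sided, Benjamini-Hochberg over the genes of a comparison, with 0.05 as the threshold. CPM are edgeR's, computed with TMM factors. Another scaling moved the median of all genes by at most 0.087 on the log2 scale.

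A mouse code links the tissues: 14 of 16 mice gave both. Pairing was taken from these codes. Deviations from the group means, over 11945 genes, correlated between the tissues of a mouse with a median r of 0.122 (-0.128 to 0.371), over 0.1 in 8 of 14 pairs, and 9 of 14 had their own mouse as the best match within the condition. The main fits had no block. In alternatives the mouse was a fixed effect in edgeR or a random effect through limma's duplicateCorrelation.

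Gene lists (31, with 519 members) were drawn up from the labels and general knowledge. Their members called by edgeR were counted, over all genes and adjusted over the list alone, and camera (limma 3.58.1, preset correlation 0.01, voom log2 CPM) compared each list with other genes, adjusted over lists and the 6 LPS comparisons, and over the other comparisons as a second family. Of 31 lists camera called 17, 18 and 17 in the hippocampus at 6, 12 and 24 h and 18, 16 and 16 in the cortex. With an estimated correlation 9, 8, 7, 10, 8 and 8 of these held. In these 6 comparisons they are the lists given without a preset value in the text. In the other comparisons 1 call held, hippocampal neuron genes between saline tissues. Fry was run as an alternative.

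Named genes were, for each LPS comparison, the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 log2 CPM and every LPS library beyond every saline library (5.7% of genes by chance), without predicted genes; up to 4 members of each list, called ones by size first, then uncalled ones by p; and always Il1b, Tnf, Ccl2, Cxcl10, Lcn2, Gfap, P2ry12, Fkbp5 and Ache. For the other comparisons they were the 6 largest called differences in each direction at the same mean level, and list members. Not every such gene is printed.

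Alternatives set beforehand were DESeq2 size factors, library totals alone, no filter, a stricter filter (1 CPM and 10 reads in 4 libraries), DESeq2 1.42.0, limma-voom with quality weights, a fit of the compared groups alone, both tissues in 1 fit, each library left out in turn, the block, fry, the estimated correlation, and overlaps of genes with an absolute log2 fold change of at least 1. Added after seeing the data were thinning to equal depth, the log2 mitochondrial or ribosomal protein share as covariates, protein-coding genes alone, and leaving out together the 3 libraries with a Ttr share over 0.1% or a mitochondrial share over 11%. Shared calls were set beside unchanged groups simulated against the same saline libraries (10 simulations).

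The fits were tested on simulated counts with known changes of 1.5, 2 and 4-fold. They recovered 76.1%, 89.6% and 100% at 6 h in the hippocampus (8 false of 185 calls, 17110 genes), 67.2%, 86.6% and 98.5% at 6 h in the cortex (8 of 176, 16961 genes), 76.1%, 91% and 100% for 24 h against 6 h in the hippocampus (11 of 189, 17097 genes) and 50.7%, 79.1% and 98.5% for the tissue difference at 6 h (5 of 157, 17485 genes). In the first, camera called the changed and 0 of 30 unchanged lists. Correlated genes were untested.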

Results

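RNA sequencing measured gene expression in 30 libraries from the hippocampus and frontal cortex of adult male C57BL/6J mice, an inbred laboratory strain, in a model of Gulf War Illness. All mice had received corticosterone (CORT), the main glucocorticoid stress hormone of rodents, at 200 mg/L in drinking water with 0.6% ethanol for 7 days. On day 8 they were given diisopropyl fluorophosphate (DFP), an organophosphate that inhibits acetylcholinesterase, at 4 mg/kg. Further 7-day courses of CORT alternated with weeks without it, over 5 weeks in total. At the end mice were injected with saline or with lipopolysaccharide (LPS), a component of the bacterial outer membrane that triggers systemic inflammation, at 0.5 mg/kg. Tissue was collected 6 h after saline (3 libraries per tissue) and 6, 12 or 24 h after LPS (4 libraries per tissue and time). No group without CORT and DFP was analysed here, so the comparisons are of LPS with saline, of times and of tissues in mice with that history. Saline tissue was collected at 6 h alone, so comparisons of the 12 h and 24 h groups with saline also differ in collection time.

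The deposited counts summed to 16826882 to 33034295 per library. In the hippocampus the saline libraries held 26818493 to 29896427 counts and the LPS libraries 18910055 to 26366879. In the cortex the saline libraries held 20678035 (mouse A223), 16826882 (A224) and 33034295 (A226), and the LPS libraries 18479503 to 23762726. Ttr, which encodes the choroid plexus protein transthyretin, took 0.115% of counts in hippocampus saline A222 and 0.226% in hippocampus LPS 12 h A261, against at most 0.096% in the other libraries. Mitochondrially encoded transcripts took 11.45% of counts in cortex LPS 6 h A240, against 6.54 to 9.642% in the others. Below, expression is in CPM, counts scaled to library size, as mean ± SD (saline n = 3, each LPS group n = 4), and log2 fold changes carry their standard errors from edgeR. Ratios, given for some genes with few saline counts, carry 95% exact intervals, which cover counting error alone.

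The first comparison asked what LPS did to the hippocampus within 6 h. Most cytokine and interferon-stimulated genes measured rose (11 of 12 and 23 of 28), and 13 of 20 glucocorticoid-responsive genes fell. Lcn2, which encodes the iron-sequestering acute phase protein lipocalin 2 (ENSMUSG00000026822.14, GRCm38 chromosome 2, 32384633 to 32388252), was at 11.6 ± 1.61 CPM (SD, n = 4) after LPS and 0.227 ± 0.079 CPM (SD, n = 3) after saline (log2 fold change 5.65 ± 0.27 SE, adjusted p = 1.49e-11). Sele, the endothelial adhesion receptor E-selectin (ENSMUSG00000026582.6, chromosome 1, 164048234 to 164057677), was at 5.3 ± 1.43 against 0.0229 ± 0.0198 CPM, a ratio of 220 (60.5 to 1820; adjusted p = 9.35e-08). Plin4, a lipid droplet coat protein whose gene responds to glucocorticoids (ENSMUSG00000002831.13, chromosome 17, 56100591 to 56109803), fell from 40.7 ± 21.9 to 5.41 ± 1.97 CPM (log2 fold change -2.89 ± 0.37, adjusted p = 0.00049). These were chosen with all 4 LPS libraries beyond all 3 saline libraries.

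Among the 12 measured cytokine and chemokine genes, 11 rose at 6 h in the hippocampus (11 adjusted over the list alone; camera adjusted p = 0.0115 with an estimated correlation). Il1b, the cytokine interleukin-1 beta (ENSMUSG00000027398.13, chromosome 2, 129364570 to 129371139), reached 3.93 ± 2.02 CPM against 0.0716 ± 0.0352, a ratio of 55.6 (25.3 to 152; adjusted p = 5.5e-06). The monocyte attractant Ccl2 was at 1.95 ± 1.01 against 0.0345 ± 0.0347 CPM (ratio 55.4, 18.6 to 271, adjusted p = 0.00187), and Tnf at 0.606 ± 0.239 against 0.0359 ± 0.0347 CPM (ratio 16.7, 5.42 to 83.8, adjusted p = 0.000111). Of 28 interferon-stimulated genes, 23 rose (27 adjusted over the list alone; median log2 fold change 1.59; adjusted p = 0.0221 with an estimated correlation). The transcription factor gene Irf7 rose by 3.39 ± 0.27 on the log2 scale, the guanylate-binding GTPase gene Gbp2 by 3.29 ± 0.3 and Ifi44 by 4.32 ± 0.34 (adjusted p = 4.37e-07, 6.29e-06 and 1.2e-08). On the NF-kB feedback and acute phase list 11 of 22 genes rose and 1 fell (15 and 1 adjusted over the list alone; adjusted p = 0.0183 with an estimated correlation). Of 20 endothelial activation genes 10 rose (13 adjusted over the list alone; adjusted p = 0.0205 with an estimated correlation). Selp, the adhesion receptor P-selectin, was at 4.56 ± 0.515 against 0.0231 ± 0.04 CPM (ratio 193, 53 to 1600, adjusted p = 7.4e-10). Of 11 genes of neutrophils and monocytes 7 rose (9 adjusted over the list alone; adjusted p = 0.0115 with an estimated correlation). Without saline A222, which held both saline counts of Selp, that gene was at least 84.7-fold higher than 3 counts over the remaining saline libraries. The ratios of Ccl2 and Tnf were then 109 (19.4 to 4350) and 33.1 (5.68 to 1330). Without saline A224 those of Selp and Tnf were 126 (34.6 to 1040) and 10.9 (3.54 to 54.7).

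Of 20 glucocorticoid-responsive genes, 13 fell and 1 rose at 6 h in the hippocampus (15 and 1 adjusted over the list alone; median log2 fold change -0.5; adjusted p = 0.0282 with an estimated correlation). The riser was Nr3c1, the glucocorticoid receptor gene, named after its values were seen. Hif3a, an inhibitory member of the hypoxia-inducible factor family (ENSMUSG00000004328.15, chromosome 7, 17031507 to 17062427), fell from 11.8 ± 3.5 to 1.41 ± 0.318 CPM (log2 fold change -3.03 ± 0.3, adjusted p = 7.92e-06). Fkbp5, a co-chaperone of the glucocorticoid receptor (ENSMUSG00000024222.16, chromosome 17, 28399094 to 28517527), fell from 137 ± 22.9 to 80.2 ± 6.89 CPM (-0.78 ± 0.1, adjusted p = 0.000103). Of 16 blood-brain barrier and endothelial identity genes 5 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.00121, and adjusted p = 0.0687 with an estimated correlation). Those that fell included Mfsd2a, a lysophospholipid transporter of brain endothelium (ENSMUSG00000028655.11, chromosome 4, 122946850 to 122961188; -0.92 ± 0.13, adjusted p = 0.000159). The number of its genes called lower was 3 without saline A222, A224 or LPS 6 h A242, and 2 without A241 or A243.

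Glial genes changed in part at 6 h in the hippocampus. Of 21 reactive astrocyte genes 9 rose (14 adjusted over the list alone; adjusted p = 0.0213 with an estimated correlation). Gfap, the astrocyte intermediate filament gene, was at 318 ± 21.5 against 231 ± 52.1 CPM and did not pass (0.46 ± 0.15, adjusted p = 0.114). It passed without saline A226 (0.66). Of 17 activated microglia genes 8 rose (9 adjusted over the list alone; adjusted p = 0.0253 with an estimated correlation). Without saline A222 or LPS 6 h A241 or A243, 5 did. Of 16 homeostatic microglia genes 3 fell (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00024, and adjusted p = 0.36 with an estimated correlation). Mertk, a receptor for apoptotic cells carried by microglia and astrocytes, fell from 47.7 ± 7.38 to 29.9 ± 1.15 CPM (-0.67 ± 0.08, adjusted p = 1.23e-05). P2ry12, the ADP receptor of resting microglia, was at 7.46 ± 2.09 against 11.5 ± 5.2 CPM (adjusted p = 0.333). Complement and antigen presentation genes rose in 12 of 19 cases (14 adjusted over the list alone; adjusted p = 0.0221 with an estimated correlation; 7 without saline A224).

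At 6 h in the hippocampus edgeR called 512 genes higher and 372 lower among 17289 tested (2515 at an unadjusted p under 0.05), of which 195 and 36 differed by at least 2-fold. Without saline A222, 165 genes were called lower, without saline A224 319 higher and 200 lower, and without LPS 6 h A243 2.3e+02 lower. With hippocampus saline A222 and LPS 12 h A261, the libraries with the higher Ttr shares, left out, 396 were higher and 174 lower.

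At 12 h the question was which parts of the hippocampal response lasted, and which arose later. Of the lists, 27 of 28 interferon-stimulated genes were higher, 17 of 20 glucocorticoid-responsive genes lower, and astrocyte homeostasis genes moved in both directions. Cxcl10, an interferon-induced T cell attractant (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889), was at 4.07 ± 1.27 against 0.0997 ± 0.113 CPM in saline (ratio 42.9, 21.5 to 100; adjusted p = 4.63e-05). Gfap (ENSMUSG00000020932.14, chromosome 11, 102887336 to 102900912) rose from 231 ± 52.1 to 535 ± 44.1 CPM (1.21 ± 0.15, adjusted p = 0.000151). Rtp1, a chaperone of odorant receptors (ENSMUSG00000033383.6, chromosome 16, 23429133 to 23433960), fell from 10.5 ± 3.26 to 0.717 ± 0.123 CPM (-3.87 ± 0.33, adjusted p = 8.7e-07).

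Of 28 interferon-stimulated genes 27 rose at 12 h in the hippocampus (28 adjusted over the list alone; median log2 fold change 2.59; adjusted p = 0.0213 with an estimated correlation). Cytokine and chemokine genes rose in 11 of 12 cases, complement and antigen presentation genes in 16 of 19 and neutrophil and monocyte genes in 7 of 11 (11, 16 and 7 adjusted over the list alone; adjusted p = 0.0115, 0.0205 and 0.0213 with an estimated correlation). The monocyte attractant gene Ccl12 rose to 4.78 ± 0.854 from 0.0615 ± 0.058 CPM (ratio 82.2, 34.9 to 254; adjusted p = 2.36e-10). Of 20 endothelial activation genes 14 rose and 1 fell (15 and 3 adjusted over the list alone; adjusted p = 0.0239 with an estimated correlation), Sele being at 3.41 ± 0.937 CPM (ratio 148, 40.7 to 1230; adjusted p = 2.38e-07). NF-kB feedback and acute phase genes rose in 9 of 22 cases and fell in 1 (12 and 2 adjusted over the list alone; camera adjusted p = 3.7e-08, and adjusted p = 0.058 with an estimated correlation). Scgb3a1, a secretoglobin (ENSMUSG00000064057.12, chromosome 11, 49663610 to 49665118), was at 3.86 ± 0.469 against 0.037 ± 0.0385 CPM (ratio 112, 38 to 546; adjusted p = 2.67e-11). Without saline A226 the ratios of Cxcl10, Ccl12 and Scgb3a1 were 118 (32.5 to 979), 141 (38.9 to 1170) and 232 (41.3 to 9170). That of Scgb3a1 was 73.9 (25.1 to 360) without A222, and that of Ccl12 53.6 (22.8 to 166) without A224.

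Glucocorticoid-responsive genes fell in 17 of 20 cases at 12 h in the hippocampus, and Nr3c1 rose (17 and 1 adjusted over the list alone; median -0.76; adjusted p = 0.0282 with an estimated correlation). Plin4 was at 1.89 ± 0.324 CPM (-4.43 ± 0.42, adjusted p = 2.67e-05), Hif3a at 0.939 ± 0.387 CPM (-3.62 ± 0.32, adjusted p = 9.82e-07) and Fkbp5 at 75.4 ± 6.66 CPM (-0.87 ± 0.1, adjusted p = 1.78e-05). Of 16 blood-brain barrier and endothelial identity genes 8 fell and 2 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.00489, and adjusted p = 0.109 with an estimated correlation). Mfsd2a fell to 9.89 ± 0.563 from 37.3 ± 8.06 CPM (-1.92 ± 0.13, adjusted p = 4.95e-08).

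Of 21 reactive astrocyte genes 14 rose at 12 h in the hippocampus (16 rose and 2 fell adjusted over the list alone; adjusted p = 0.0343 with an estimated correlation). Astrocyte homeostasis genes moved apart, with 3 of 12 higher and 4 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.386). The water channel gene Aqp4 rose by 0.6 ± 0.06 (adjusted p = 1.85e-07), while the gap junction gene Gjb6 (-0.97 ± 0.09, adjusted p = 2.17e-07) and the glutamine synthetase gene Glul (-0.57 ± 0.05, adjusted p = 1.18e-08) fell. Of 17 activated microglia genes 11 rose (12 adjusted over the list alone; adjusted p = 0.0239 with an estimated correlation). Homeostatic microglia genes were split, with 4 of 16 higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.108). Fcrls, an Fc receptor-like gene of microglia (ENSMUSG00000015852.13, chromosome 3, 87250758 to 87263738), rose from 3.8 ± 2.47 to 18.3 ± 2.99 CPM (2.3 ± 0.32, adjusted p = 0.000454; 2.95 without saline A226). Oxidative stress genes rose in 3 of 14 cases and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0438, and adjusted p = 0.107 with an estimated correlation). Of 12 genes of meninges and fibroblasts 5 rose (6 adjusted over the list alone; camera adjusted p = 0.000119, and adjusted p = 0.211 with an estimated correlation). Without saline A222 or LPS 12 h A261, the libraries with the higher Ttr shares, 3 did.

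Neuronal and synaptic genes fell in 6 of 23 cases and rose in 1 at 12 h in the hippocampus (7 and 1 adjusted over the list alone; camera adjusted p = 0.00149, and adjusted p = 0.204 with an estimated correlation). Of them 3 fell without saline A222 or A226 or LPS 12 h A258 or A261. At 12 h edgeR called 1049 genes higher and 1085 lower (4120 at an unadjusted p under 0.05), of which 330 and 76 differed by at least 2-fold. Scaled by library totals alone the split was 1350 higher and 693 lower, 66.1% higher against 49.2%. Without saline A222 654 genes were lower, and 723 were higher and 518 lower without A222 and LPS 12 h A261.

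At 24 h the hippocampus was asked for what persisted a day after LPS. In it 13 of 16 homeostatic microglia genes and 27 of 28 interferon-stimulated genes stood above saline. P2ry12 (ENSMUSG00000036353.13, chromosome 3, 59216272 to 59262871) rose from 11.5 ± 5.2 to 28.1 ± 1.89 CPM (1.3 ± 0.26, adjusted p = 0.00523). It missed the threshold in the fit of both tissues together (adjusted p = 0.0633). Fcrls reached 29.2 ± 4.5 CPM (2.97 ± 0.31, adjusted p = 4.65e-05; 3.62 without saline A226), and Olfml3, a secreted protein gene of microglia, 41.5 ± 6.31 against 11.7 ± 2.42 CPM (1.83 ± 0.14, adjusted p = 3.95e-07). In all, 13 of 16 homeostatic microglia genes rose and 1, Mertk, named after its value was seen, fell (15 and 1 adjusted over the list alone; median 1.04; adjusted p = 0.0314 with an estimated correlation).

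Interferon-stimulated genes rose in 27 of 28 cases at 24 h in the hippocampus (28 adjusted over the list alone; median 2.46; adjusted p = 0.0235 with an estimated correlation). Irf7 was at 11.1 ± 2.72 against 0.806 ± 0.0527 CPM (3.78 ± 0.26, adjusted p = 3.62e-08). Complement and antigen presentation genes rose in 14 of 19 cases, cytokine and chemokine genes in 8 of 12 and neutrophil and monocyte genes in 7 of 11 (15, 8 and 7 adjusted over the list alone; adjusted p = 0.0213, 0.0239 and 0.0239 with an estimated correlation). Tnf, at 0.0692 ± 0.0299 CPM against 0.0359 ± 0.0347, did not pass (adjusted p = 0.615). Activated microglia genes rose in 10 of 17 cases and fell in 2, and endothelial activation genes rose in 13 of 20 and fell in 2 (13 and 2, and 14 and 3, adjusted over the list alone; adjusted p = 0.0241 and 0.0461 with an estimated correlation). The inhibitory Fc receptor gene Fcgr2b rose by 2.17 ± 0.18 (adjusted p = 1.17e-08), and Sele was at 1.93 ± 0.766 CPM (ratio 84.2, 23 to 701; adjusted p = 3.19e-06). NF-kB feedback and acute phase genes rose in 7 of 22 cases and fell in 1 (12 and 3 adjusted over the list alone; camera adjusted p = 0.000253, and adjusted p = 0.213 with an estimated correlation).

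Glucocorticoid-responsive genes fell in 15 of 20 cases at 24 h in the hippocampus, and Nr3c1 rose (15 and 1 adjusted over the list alone; median -0.7; camera adjusted p = 2.11e-13, and adjusted p = 0.0607 with an estimated correlation). Plin4 was at 1.1 ± 0.457 CPM (-5.18 ± 0.46, adjusted p = 1.28e-05) and Fkbp5 at 74.3 ± 3.72 CPM (-0.89 ± 0.1, adjusted p = 1.2e-05). Sult1a1, a sulfotransferase gene, fell from 25.2 ± 6.94 to 2.74 ± 0.637 CPM (-3.19 ± 0.18, adjusted p = 2.21e-09), and Rtp1 to 0.744 ± 0.524 CPM (-3.78 ± 0.33, adjusted p = 1.04e-06; -4.43 without LPS 24 h A276). Among 16 blood-brain barrier and endothelial identity genes 3 fell and 2 rose (3 and 3 adjusted over the list alone; camera adjusted p = 0.975).

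Of 21 reactive astrocyte genes 9 rose and 2 fell at 24 h in the hippocampus (10 and 2 adjusted over the list alone; camera adjusted p = 0.000555, and adjusted p = 0.247 with an estimated correlation). Gfap was at 495 ± 78 CPM (1.1 ± 0.15, adjusted p = 0.000298). Astrocyte homeostasis genes fell in 5 of 12 cases and rose in 3 (5 and 3 adjusted over the list alone; camera adjusted p = 0.0418, and adjusted p = 0.482 with an estimated correlation). Aldoc, the aldolase of astrocytes, fell from 1130 ± 24.9 to 743 ± 50.2 CPM (-0.6 ± 0.05, adjusted p = 3.27e-09), while Aqp4 rose by 0.75 ± 0.06 (adjusted p = 5.12e-09). Of 16 myelin and oligodendrocyte genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.3; camera adjusted p = 2.66e-05, and adjusted p = 0.222 with an estimated correlation). Neuronal and synaptic genes fell in 6 of 23 cases and rose in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.000272, and adjusted p = 0.137 with an estimated correlation). Among 15 genes of hippocampal neurons 5 fell and 2 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.0489, and adjusted p = 0.435 with an estimated correlation).

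At 24 h in the hippocampus edgeR called 1168 genes higher and 1141 lower (4403 at an unadjusted p under 0.05), of which 348 and 88 differed by at least 2-fold. Library totals alone gave 1613 higher and 737 lower, 68.6% higher against 50.6%. Without saline A222, the saline library with the higher Ttr share, 661 genes were called lower.

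**Figure D1:**
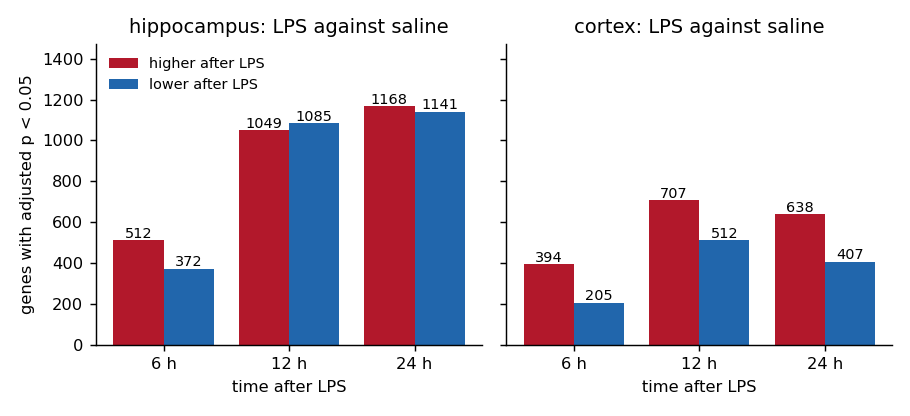
Bars show the number of genes called higher and lower (adjusted p under 0.05, edgeR) in each LPS group against saline, by tissue and hours after LPS. The hippocampus had 512, 1049 and 1168 genes higher at 6, 12 and 24 h, and the cortex 394, 707 and 638.

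The cortex was then examined for its response within 6 h. Cytokine and neutrophil genes rose in 11 of 14 and 11 of 16 cases, and 8 of 20 glucocorticoid-responsive genes fell. S100a9, a calcium-binding protein of neutrophils and monocytes (ENSMUSG00000056071.12, chromosome 3, 90692632 to 90695721) was at 8.12 ± 1.39 CPM after LPS and 0.111 ± 0.166 CPM after saline (ratio 80.5, 38.8 to 201; adjusted p = 9.4e-07). Selp (ENSMUSG00000026580.16, chromosome 1, 164115264 to 164150026) was at 5.88 ± 1.74 against 0.0104 ± 0.0181 CPM (ratio 409, 73 to 16200; adjusted p = 1.7e-06). Lcn2 was at 18.7 ± 4.67 against 0.276 ± 0.199 CPM (log2 fold change 5.98 ± 0.55, adjusted p = 4.13e-05). Hif3a fell from 11.3 ± 1.14 to 1.34 ± 0.462 CPM (-3.08 ± 0.23, adjusted p = 4.61e-07). These too were chosen with all 4 LPS libraries beyond all 3 saline libraries. Without saline A226, which held the single saline count of Selp, that gene was at least 72.4-fold higher than 3 counts over the remaining saline libraries. The ratio of S100a9 was then 49.9 (22.8 to 137), and 398 (71.2 to 15800) without A223.

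Of 14 cytokine and chemokine genes 11 rose at 6 h in the cortex (13 adjusted over the list alone; adjusted p = 0.0213 with an estimated correlation). Il1b was at 6.07 ± 2.68 against 0.417 ± 0.162 CPM (3.86 ± 0.6, adjusted p = 0.00183) and Cxcl10 at 1.52 ± 0.481 against 0.112 ± 0.0465 CPM (3.64 ± 0.54, adjusted p = 0.000555). Tnf was at 0.927 ± 0.25 against 0.0272 ± 0.0254 CPM (ratio 32.2, 8.6 to 271; adjusted p = 0.00328). Interferon-stimulated genes rose in 18 of 28 cases (25 adjusted over the list alone; median 1.42; adjusted p = 0.0426 with an estimated correlation), with Irf7 at 14.4 ± 4.47 against 1.7 ± 0.703 CPM (2.99 ± 0.39, adjusted p = 0.000565). NF-kB feedback and acute phase genes rose in 13 of 22 cases (16 adjusted over the list alone; adjusted p = 0.0239 with an estimated correlation). Neutrophil and monocyte genes rose in 11 of 16 cases (13 adjusted over the list alone; adjusted p = 0.0115 with an estimated correlation), and endothelial activation genes in 11 of 20 (14 adjusted over the list alone; adjusted p = 0.0239 with an estimated correlation). Complement and antigen presentation genes rose in 10 of 21 cases (12 adjusted over the list alone; adjusted p = 0.0221 with an estimated correlation), 6 without saline A223 or A226. Oxidative stress genes rose in 3 of 14 cases (5 adjusted over the list alone; adjusted p = 0.0282 with an estimated correlation).

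Glucocorticoid-responsive genes fell in 8 of 20 cases at 6 h in the cortex (11 adjusted over the list alone; median -0.51; adjusted p = 0.0213 with an estimated correlation). Plin4 fell from 55.8 ± 12.3 to 10.8 ± 3 CPM (-2.37 ± 0.24, adjusted p = 5.42e-05) and Fkbp5 from 100 ± 18.3 to 48.2 ± 7.68 CPM (-1.05 ± 0.14, adjusted p = 0.000209). Of 16 blood-brain barrier and endothelial identity genes 3 fell (8 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.000555, and adjusted p = 0.119 with an estimated correlation). Reactive astrocyte genes rose in 11 of 21 cases (15 adjusted over the list alone; adjusted p = 0.0412 with an estimated correlation), 5 without saline A223 or A226. Gfap rose from 124 ± 10.5 CPM (0.84 ± 0.15, adjusted p = 0.00364). Of 18 activated microglia genes 7 rose (12 adjusted over the list alone; adjusted p = 0.0452 with an estimated correlation), 3 without saline A223 and 1 without A226. Of 16 homeostatic microglia genes 2 fell (2 adjusted over the list alone; camera adjusted p = 2.1e-05, and adjusted p = 0.395 with an estimated correlation). They were Mertk (-0.62 ± 0.1, adjusted p = 0.00158) and Tgfbr1, a transforming growth factor receptor gene (-0.72 ± 0.13, adjusted p = 0.00273).

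At 6 h in the cortex edgeR called 394 genes higher and 205 lower among 17111 tested (3250 at an unadjusted p under 0.05), of which 199 and 35 differed by at least 2-fold. Without saline A223 112 were lower, without saline A226 211 were higher and 120 lower, and without LPS 6 h A242 2.6e+02 and 114. Without LPS 6 h A240, the library with the high mitochondrial share, 127 were lower, and without LPS 6 h A241 409.

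At 12 h the cortex, like the hippocampus, was compared with its saline group at 6 h. All 28 interferon-stimulated genes were higher and 13 of 20 glucocorticoid-responsive genes lower. Cxcl10 was at 4.72 ± 1.84 against 0.112 ± 0.0465 CPM (5.27 ± 0.47, adjusted p = 1.4e-06), and Ccl12 at 5.44 ± 1.29 against 0.183 ± 0.103 CPM (4.9 ± 0.45, adjusted p = 2.01e-06). Plin4 fell to 1.8 ± 0.641 CPM (-4.96 ± 0.29, adjusted p = 1.2e-07). Rtp1 fell from 4.8 ± 1.32 to 0.532 ± 0.387 CPM (-3.2 ± 0.35, adjusted p = 1.29e-05).

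All 28 interferon-stimulated genes rose at 12 h in the cortex (28 adjusted over the list alone; median 2.48; adjusted p = 0.0213 with an estimated correlation). Complement and antigen presentation genes rose in 15 of 21 cases, neutrophil and monocyte genes in 12 of 16, endothelial activation genes in 12 of 20 and cytokine and chemokine genes in 9 of 14 (17, 13, 13 and 10 adjusted over the list alone; adjusted p = 0.0115, 0.0207, 0.0412 and 0.0426 with an estimated correlation). Tnf, at 0.255 ± 0.191 CPM, did not pass (ratio 9.28, 2.29 to 81.2; adjusted p = 0.129). NF-kB feedback and acute phase genes rose in 9 of 22 cases (10 adjusted over the list alone; camera adjusted p = 8.44e-07, and adjusted p = 0.159 with an estimated correlation). Oxidative stress genes rose in 3 of 14 cases (5 adjusted over the list alone; adjusted p = 0.0235 with an estimated correlation).

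Glucocorticoid-responsive genes fell in 13 of 20 cases at 12 h in the cortex (15 fell and 1 rose adjusted over the list alone; median -0.63; adjusted p = 0.0115 with an estimated correlation). Fkbp5 was at 35.9 ± 5.29 CPM (-1.48 ± 0.14, adjusted p = 3.63e-06) and Hif3a at 0.919 ± 0.37 CPM (-3.62 ± 0.24, adjusted p = 3.49e-08). Of 18 activated microglia genes 11 rose (12 rose and 1 fell adjusted over the list alone; adjusted p = 0.0235 with an estimated correlation), 7 without saline A226, and the Fc receptor gene Fcgr1 rose by 2.32 ± 0.19 (adjusted p = 3.07e-07). Of 16 homeostatic microglia genes 2 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0694). The risers were Fcrls, at 25.5 ± 10.3 against 5.2 ± 2.27 CPM (2.24 ± 0.42, adjusted p = 0.0063), and the fractalkine receptor gene Cx3cr1 (0.82 ± 0.16, adjusted p = 0.00288). P2ry12, at 19.2 ± 12.6 against 13.2 ± 4.61 CPM, did not pass (adjusted p = 0.653). Reactive astrocyte genes rose in 9 of 21 cases (10 adjusted over the list alone; camera adjusted p = 1.85e-06, and adjusted p = 0.171 with an estimated correlation), Gfap by 1.31 ± 0.15 (adjusted p = 4.72e-05). Of 12 astrocyte homeostasis genes 2 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.0134, and adjusted p = 0.374 with an estimated correlation). They were Gjb6 (-0.82 ± 0.06, adjusted p = 7.89e-08), Glul (-0.47 ± 0.06, adjusted p = 6.66e-05) and Aqp4 (0.41 ± 0.1, adjusted p = 0.0173), which did not pass without saline A224 or LPS 12 h A259 or A261. Of 16 blood-brain barrier and endothelial identity genes 3 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.238), with 1 lower without saline A226. The endothelial adhesion gene Esam rose by 0.9 ± 0.12 (adjusted p = 8.71e-05), and Mfsd2a fell to 8.88 ± 1.32 from 32 ± 5.33 CPM (-1.84 ± 0.13, adjusted p = 7.89e-08).

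Of the 13 mitochondrially encoded transcripts 3 fell at 12 h in the cortex (10 adjusted over the list alone; median -0.43; camera adjusted p = 4.2e-07, and adjusted p = 0.254 with an estimated correlation). Their share of all counts was 7.379% on average at 12 h against 8.958% in saline and 9.226% at 6 h. Neuronal and synaptic genes fell in 2 of 23 cases (7 adjusted over the list alone; camera adjusted p = 2.52e-05, and adjusted p = 0.0627 with an estimated correlation). Meningeal and fibroblast genes fell in 3 of 12 cases and rose in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.031, and adjusted p = 0.482 with an estimated correlation). At 12 h in the cortex edgeR called 707 genes higher and 512 lower (3332 at an unadjusted p under 0.05), of which 307 and 70 differed by at least 2-fold. Library totals alone gave 1158 higher and 316 lower, 78.6% higher against 58%. Without saline A223 465 were higher and 302 lower, without saline A226 448 and 307. With the mitochondrial share as a covariate 473 were higher and 266 lower.

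At 24 h the cortical response was measured a last time. Scgb3a1, at 4.07 ± 0.473 against 0.037 ± 0.0325 CPM (ratio 147, 40.3 to 1220; adjusted p = 6.71e-09), and Cxcl10, at 3.38 ± 1.01 CPM (4.79 ± 0.49, adjusted p = 6.32e-06), were still raised. Plin4, at 1.49 ± 0.645 CPM (-5.21 ± 0.3, adjusted p = 1.02e-07), and Fkbp5, at 33.1 ± 2.89 CPM (-1.59 ± 0.14, adjusted p = 1.8e-06), were still lowered. Il1b, at 1.65 ± 0.766 against 0.417 ± 0.162 CPM, did not pass (1.99 ± 0.67, adjusted p = 0.116), nor did Tnf, at 0.372 ± 0.354 CPM (ratio 13.6, 3.47 to 117; adjusted p = 0.0516). Tnf passed without LPS 24 h A274 (fitted log2 fold change 3.74, against 3.45) or A275 (3.73) and stood at 2.68 without A278. The ratio of Scgb3a1 was 77.9 (21.4 to 646) without saline A226 and 2.2e+02 (39.8 to 8840) without A224.

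Interferon-stimulated genes rose in 25 of 28 cases at 24 h in the cortex (27 adjusted over the list alone; median 2.15; adjusted p = 0.0213 with an estimated correlation). Complement and antigen presentation genes rose in 15 of 21 cases, 9 without saline A223 or A226, cytokine and chemokine genes in 7 of 14, endothelial activation genes in 10 of 20 and neutrophil and monocyte genes in 8 of 16 (17, 11, 14 and 11 adjusted over the list alone; adjusted p = 0.0115, 0.0343, 0.0376 and 0.0205 with an estimated correlation). NF-kB feedback and acute phase genes rose in 9 of 22 cases (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.41e-08, and adjusted p = 0.107 with an estimated correlation). Glucocorticoid-responsive genes fell in 13 of 20 cases (14 fell and 1 rose adjusted over the list alone; median -0.77; adjusted p = 0.0115 with an estimated correlation), and 8 fell with the mitochondrial share as a covariate. Oxidative stress genes rose in 3 of 14 cases (4 adjusted over the list alone; adjusted p = 0.0239 with an estimated correlation).

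Of 18 activated microglia genes 10 rose at 24 h in the cortex (12 rose and 1 fell adjusted over the list alone; adjusted p = 0.0221 with an estimated correlation), 6 without saline A226 or LPS 24 h A278. Homeostatic microglia genes rose in 3 of 16 cases and fell in 1 (4 and 1 adjusted over the list alone; median 0.5; camera adjusted p = 0.00751, and adjusted p = 0.569 with an estimated correlation), Fcrls by 2.36 ± 0.42 (adjusted p = 0.00514). Reactive astrocyte genes rose in 10 of 21 cases (11 adjusted over the list alone; camera adjusted p = 9.86e-07, and adjusted p = 0.159 with an estimated correlation), 6 without saline A223 or A226, Gfap by 1.18 ± 0.15 (adjusted p = 0.000138). Of 12 astrocyte homeostasis genes Gjb6 (-0.93 ± 0.06, adjusted p = 1.89e-08) and Glul (-0.43 ± 0.06, adjusted p = 0.000161) fell and Aqp4 rose (0.51 ± 0.1, adjusted p = 0.00406), with 3 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.117), and 2 rose without saline A226. Of 16 blood-brain barrier and endothelial identity genes 2 rose and 1 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.616), with 2 lower without saline A224 and 4 without LPS 24 h A274. They were Esam (0.85 ± 0.12, adjusted p = 0.000173), Pecam1 (0.53 ± 0.11, adjusted p = 0.0047) and Mfsd2a (-1.87 ± 0.13, adjusted p = 6.15e-08). Myelin and oligodendrocyte genes rose in 3 of 16 cases and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0073, and adjusted p = 0.496 with an estimated correlation). Mitochondrially encoded transcripts fell in 2 of 13 cases (9 adjusted over the list alone; median -0.4; camera adjusted p = 2.73e-07, and adjusted p = 0.247 with an estimated correlation), with a mean share of 7.382% of counts.

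At 24 h in the cortex edgeR called 638 genes higher and 407 lower (2832 at an unadjusted p under 0.05), of which 288 and 66 differed by at least 2-fold. Library totals alone gave 976 higher and 267 lower, 78.5% higher against 61.1%, and without saline A223 237 were called lower. With the mitochondrial share as a covariate 217 were called lower.

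**Figure D2:**
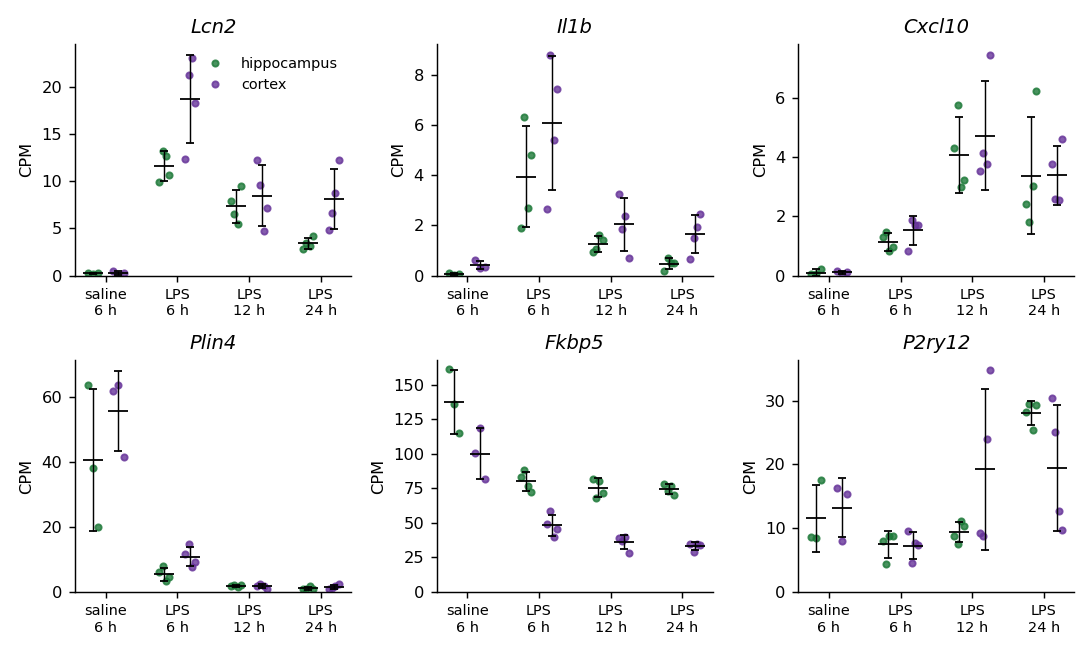
Points show expression of 6 genes in each library (CPM), by tissue and group, with black bars for the mean ± SD of a group (saline n = 3, each LPS group n = 4). Lcn2 stood at 11.6 CPM in the hippocampus and 18.7 CPM in the cortex 6 h after LPS, and Plin4 at 1.1 and 1.49 CPM at 24 h.

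The remaining lists, fixed before the data were examined, covered other cell types, quality markers and pathways. Ache, the target of DFP, was at 47.2 ± 0.401, 47.1 ± 4.55 and 52.5 ± 3.02 CPM at 6, 12 and 24 h in the hippocampus, against 48.5 ± 2.15 in saline. It was at 44 ± 3.69, 49.9 ± 9.42 and 49.4 ± 6.25 CPM in the cortex, against 47.7 ± 6.84 in saline (lowest adjusted p = 0.27). Cholinergic genes (13 measured in the hippocampus, 14 in the cortex) fell in 2 cases at 12 h and 3 at 24 h in the hippocampus and in 2 at 12 h in the cortex (2, then 4 with 2 higher, and 2, adjusted over the list alone). EdgeR called none in the hippocampus at 6 h (3 at an unadjusted p under 0.05; 0 by DESeq2, 2 by limma-voom), in the cortex at 6 h (3; 0 and 0) or at 24 h (2; 0 and 0). Circadian clock genes, 17 on the list, rose and fell in 0 and 2, 3 and 4, and 4 and 4 cases at 6, 12 and 24 h in the hippocampus (0 and 3, 3 and 4, 5 and 4 adjusted over the list alone). In the cortex they did so in 0 and 1, 3 and 2, and 1 and 1 (0 and 2, 4 and 2, 2 and 2). The clock output gene Dbp rose at 12 and 24 h (adjusted p at most 0.000941). The rises were 0.41 ± 0.08 and 0.51 ± 0.08 in the hippocampus and 0.57 ± 0.07 and 0.48 ± 0.07 in the cortex. Collection time also differed. Camera called neither of these 2 lists against saline (lowest adjusted p = 0.0766 for the clock list).

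Uhrf1, which maintains DNA methylation in dividing cells, rose at 24 h in the hippocampus from 0.443 ± 0.148 to 2.26 ± 0.451 CPM (2.34 ± 0.28, adjusted p = 2.67e-06). DNA methylation genes, 16 on the list, rose in 1 and 2 cases at 12 and 24 h in the hippocampus and in 3, 2 and 1 at 6, 12 and 24 h in the cortex (1, then 3 with 1 lower, then 3 with 1 lower, 2 and 2 adjusted over the list alone). At 6 h in the hippocampus edgeR called 0 (2 at an unadjusted p under 0.05; 0 by DESeq2, 2 by limma-voom). Of 19 immediate early genes, 1 rose at 6 h, 3 fell at 12 h and 2 rose at 24 h in the hippocampus (1, 3 and 2 adjusted over the list alone; camera adjusted p = 0.0112, 0.0178 and 0.0633, and adjusted p = 0.522, 0.542 and 0.629 with an estimated correlation). In the cortex edgeR called 0 of them at each time (1 or 2 at an unadjusted p under 0.05; 0 by DESeq2, at most 1 by limma-voom). Of 18 heat shock and chaperone genes, 1 rose at 6 h, 1 rose and 2 fell at 12 h and 2 fell at 24 h in the hippocampus (1, then 7 and 2, then 2 adjusted over the list alone; camera adjusted p = 2.73e-06, 0.00691 and 0.0397, and adjusted p = 0.377, 0.584 and 0.682 with an estimated correlation). In the cortex 2 rose at 6 h and at 24 h (8 and 7 adjusted over the list alone; camera adjusted p = 0.000228 and 0.000408, and adjusted p = 0.468 and 0.482 with an estimated correlation). EdgeR called 0 at 12 h there (6 at an unadjusted p under 0.05; 1 by DESeq2, 7 by limma-voom). Those that fell at 24 h were Hspa1a and Hspa1b, near-identical copies whose reads cannot be assigned to one of them with certainty.

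Of 10 oligodendrocyte precursor genes 4 rose and 1 fell at 24 h in the hippocampus (4 and 3 adjusted over the list alone), and 1 rose in the cortex (1 adjusted over the list alone). Of 14 neocortical neuron genes 1 rose and 2 fell at 24 h in each tissue (1 and 2 in the hippocampus, 1 and 4 in the cortex, adjusted over the list alone). Of 12 pericyte and mural cell genes 1 rose in each (0 and 2 adjusted over the list alone). Of 12 striatal neuron genes in the hippocampus 1 fell (1 adjusted over the list alone). Camera called none of these 4 lists at 24 h (lowest adjusted p = 0.053). At earlier times it called, as lower in the cortex, precursor genes at 6 h (adjusted p = 0.0196, and adjusted p = 0.107 with an estimated correlation). It did so for neocortical neuron genes at 6 and 12 h (adjusted p = 0.0452 and 0.0397, and adjusted p = 0.452 and 0.442 with an estimated correlation). In the cortex edgeR called 0 of 13 striatal genes at any time (0 at an unadjusted p under 0.05, by DESeq2 or by limma-voom), with medians of -0.28, -0.21 and -0.11 against an upward camera direction. EdgeR called 0 of 24 oxidative phosphorylation genes in any of the 6 comparisons (at most 4 at an unadjusted p under 0.05; 0 by DESeq2, at most 1 by limma-voom). It called 0 of 7 red blood cell genes (at most 3; at most 1 and 1) and, in the hippocampus, 0 of 13 mitochondrially encoded transcripts (at most 1; 0 and 0). Choroid plexus and ependymal genes, 16 on the list, were called by edgeR in 0 cases outside the cortex at 6 h (at most 7 at an unadjusted p under 0.05, at 24 h in the hippocampus, where DESeq2 called 3; 0 by limma-voom). In the cortex at 6 h the ciliary gene Ccdc153 rose (1.12 ± 0.29, adjusted p = 0.0353; 1 adjusted over the list alone), but missed the threshold without saline A223 (1.02), A224 (1.1) or A226 (1.28), or LPS A240 (1.03) or A242 (0.93). Camera called choroid plexus genes as lower at 6 and 24 h in the hippocampus and at 12 and 24 h in the cortex. It called red blood cell genes as higher at 6 and 12 h in the hippocampus and oxidative phosphorylation genes at 6 h in the cortex. These calls had adjusted p values from 9.42e-05 to 0.0438, and at the lowest adjusted p = 0.496 with an estimated correlation. Of the lymphocyte genes measured, 2 in the hippocampus and 3 in the cortex, the immunoglobulin gene Ighm fell at 6 h in each tissue (1 of each list, and 1 adjusted over the list alone) and at 12 h in the hippocampus (-1.19 ± 0.24, adjusted p = 0.00468).

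**Figure D3:**
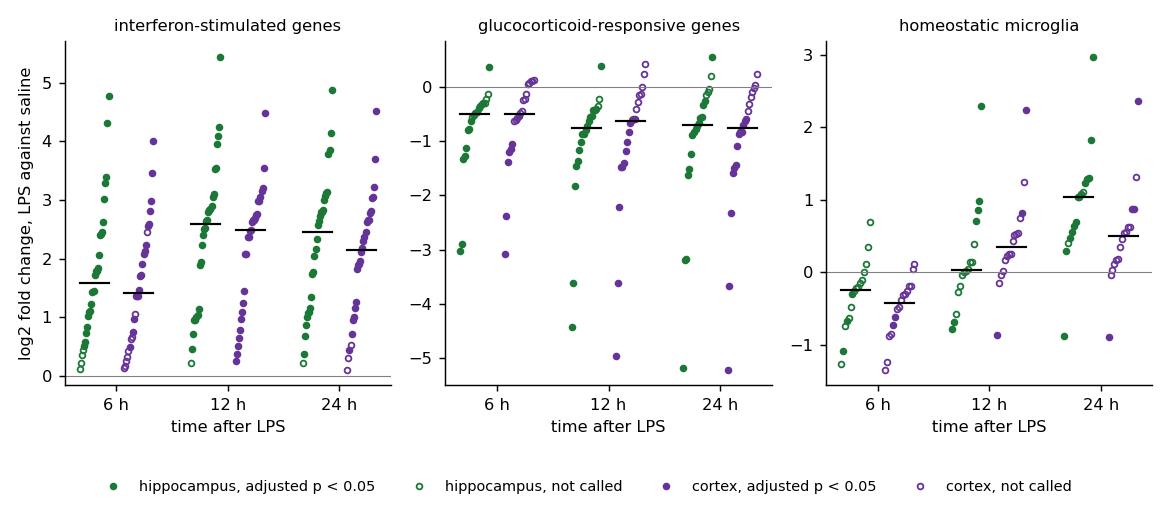
Points show the log2 fold change of each member of 3 gene lists against saline, by hours after LPS and tissue, filled where the adjusted p was under 0.05 and open where not, with a black line at the median. Homeostatic microglia genes had medians of -0.24, 0.03 and 1.04 in the hippocampus at 6, 12 and 24 h.

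LPS groups were also compared with each other, to ask how the response moved with time. In the hippocampus, between 6 and 24 h, Il1b fell from 3.93 ± 2.02 to 0.472 ± 0.208 CPM (-3.03 ± 0.39, adjusted p = 7.83e-05) and Lcn2 from 11.6 ± 1.61 to 3.43 ± 0.604 CPM (-1.76 ± 0.16, adjusted p = 2.68e-07). Itgam, an integrin of microglia and other myeloid cells, rose from 1.92 ± 0.142 to 8.59 ± 0.589 CPM (2.15 ± 0.19, adjusted p = 8.85e-08), and P2ry12 from 7.46 ± 2.09 to 28.1 ± 1.89 CPM (1.93 ± 0.25, adjusted p = 0.000555). Of 16 homeostatic microglia genes 15 rose (15 rose and 1 fell adjusted over the list alone; median 1.32; camera adjusted p = 2.9e-26, and adjusted p = 0.139 with an estimated correlation). Of 22 NF-kB feedback and acute phase genes 10 fell (13 adjusted over the list alone; adjusted p = 0.408 with an estimated correlation). In all 790 genes were higher and 850 lower at 24 h than at 6 h, and 197 higher and 173 lower at 12 h (library totals alone: 1010 and 656, 60.6% higher against 48.2%, and 240 and 138, 63.5% against 53.2%). The 370 calls at 12 h became 172 without LPS 6 h A240, 210 without A241 and 246 without A243.

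In the cortex Mfsd2a fell from 21.1 ± 0.573 CPM at 6 h to 8.88 ± 1.32 at 12 h (-1.25 ± 0.13, adjusted p = 4.44e-05) and 8.68 ± 1.43 at 24 h (-1.28 ± 0.13, adjusted p = 2.5e-05). Plin4 fell from 10.8 ± 3 to 1.8 ± 0.641 and 1.49 ± 0.645 CPM (-2.59 ± 0.3 and -2.84 ± 0.31, adjusted p = 0.000507 and 0.000258). C4b, a complement component, rose from 23.4 ± 1.66 to 40.3 ± 5.43 CPM at 12 h (0.78 ± 0.09, adjusted p = 8.71e-05). Homeostatic microglia genes rose in 5 of 16 cases at 12 h and 7 at 24 h (13 with 1 lower, and 12 with 1 lower, adjusted over the list alone; adjusted p = 0.424 and 0.408 with an estimated correlation). At 12 h 105 genes were higher and 105 lower than at 6 h, and at 24 h 135 and 178 (library totals alone: 219 and 89, 71.1% higher against 50%, and 244 and 118, 67.4% against 43.1%). The 210 calls at 12 h became 100, 139, 137 and 115 without LPS 6 h A240, A241, A242 and A243, and 97 and 95 without LPS 12 h A260 and A261. The 313 calls at 24 h became 108, 163 and 188 without LPS 6 h A240, A242 and A243, and 122, 110 and 200 without LPS 24 h A274, A275 and A276. The mitochondrial share was 8.17 to 11.45% at 6 h, then at most 8.15%. As a covariate it cannot be told from time (23 genes at 12 h, 37 at 24 h). Without libraries of high Ttr or mitochondrial share 100 and 108 differed. The ribosomal covariate gave 616 and 602, DESeq2 476 and 558, both tissues in 1 fit 674 and 893, and limma-voom 483 at 24 h.

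Calls were shared between times and tissues. In the hippocampus 431 genes were higher and 312 lower at both 6 and 12 h, 376 and 246 at both 6 and 24 h, and 708 and 692 at both 12 and 24 h, where independent lists would share 31.1 and 23.3, 34.6 and 24.6, and 70.9 and 71.6. In the cortex they were 293 and 131, 281 and 124, and 542 and 351 (16.3 and 6.1, 14.7 and 4.9, and 26.4 and 12.2). Between tissues 270 genes were higher and 123 lower in both at 6 h, 492 and 294 at 12 h, and 474 and 248 at 24 h (11.6 and 4.5, 42.4 and 32.5, 43.1 and 27). With no effect simulated at most 0.2 on average were shared. Fold changes across genes, which are not independent, correlated with r = 0.823, 0.721 and 0.802 between the hippocampal times in the same order, 0.794, 0.76 and 0.892 between the cortical times and 0.754, 0.752 and 0.737 between tissues. Simulated unchanged groups against the same saline libraries gave 0.542, 0.541 and 0.543, then 0.568, 0.57 and 0.58, and -0.007, 0.006 and -0.006. Covariances were 0.1376, 0.121 and 0.1536 (simulated 0.0196, 0.0195 and 0.0197), 0.1533, 0.1471 and 0.1842 (0.0268, 0.0269 and 0.0272), and 0.1142, 0.1393 and 0.1323 between tissues (-3e-04, 2e-04 and -2e-04). Some excess may come from shared saline libraries (3 per tissue, too few to split) and, between tissues, shared mice, not simulated. In all 6 comparisons 207 genes were higher and 70 lower.

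Whether the response differed between tissues was tested in a fit of all 30 libraries. At 6 h edgeR called 0 of 17650 genes (1031 at an unadjusted p under 0.05; 0 by DESeq2, 8 by limma-voom). At 12 h the hippocampal response was higher in 7 genes and lower in 10, and at 24 h higher in 12 and lower in 10. Rprm, a cell cycle inhibitor gene expressed in neurons, fell in the hippocampus by 0.53 at 12 h and 0.56 at 24 h, against changes of 0.41 and 0.36 in the cortex (difference -0.95 ± 0.15, adjusted p = 0.00546, and -0.91 ± 0.15, adjusted p = 0.0106). Prss23, a serine protease gene, was at a log2 fold change of 0.25 in the hippocampus and -0.72 in the cortex at 24 h (difference 0.96 ± 0.16, adjusted p = 0.0106). Camera called mitochondrially encoded transcripts higher in this difference at 12 and 24 h (10 of 13 each adjusted over the list alone; adjusted p = 1.2e-11 and 4.82e-12, and adjusted p = 0.408 with an estimated correlation at each). With the mouse as a fixed effect neither Rprm nor Prss23 passed (-0.88, -0.86 and 0.97), and the counts were 6 higher and 2 lower at 12 h and 5 and 1 at 24 h. With the mouse as a random effect in limma-voom (consensus correlation 0.11) they were 18 and 14, and 19 and 16. Library totals alone gave 4 and 13 at 12 h and 8 and 14 at 24 h, and DESeq2 size factors 3 and 7 at 12 h. The 17 calls at 12 h became 6, 4 and 10 without hippocampus saline A222, A224 and A226, 9 and 6 without hippocampus LPS A259 and A261, 2 and 9 without cortex saline A223 and A226, and 34, 11 and 9 without cortex LPS A259, A260 and A261. The 22 at 24 h became 8, 9 and 12 without hippocampus saline A222, A224 and A226, 13 without hippocampus LPS A274 or A276, 8 without cortex saline A223, and 40, 12 and 12 without cortex LPS A274, A275 and A278.

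The tissues themselves were compared in the saline groups. Dsp, a desmosome gene of dentate granule cells, was at 50.8 ± 8.54 CPM in the hippocampus and 0.56 ± 0.0767 in the cortex (6.51 ± 0.24, adjusted p = 2.8e-19). Prox1, a granule cell transcription factor, was at 92.8 ± 5.86 against 13.2 ± 0.997 (2.8 ± 0.12, adjusted p = 3.07e-18). Tbr1, a cortical transcription factor, was at 51 ± 5.61 against 174 ± 12.2 (-1.77 ± 0.11, adjusted p = 1.32e-14). Of 15 hippocampal neuron genes 13 were higher in the hippocampus (13 adjusted over the list alone; adjusted p = 0.006 with an estimated correlation). Of 16 myelin genes 15 were lower (15 adjusted over the list alone; adjusted p = 0.408 with an estimated correlation). In all 3513 genes were higher and 3039 lower. The cortex libraries differed in striatal genes, which summed to 770 CPM in saline A223, 1690 in A224 and 446 in A226.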

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

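Comparisons of times and tissues, library totals, DESeq2 size factors and leaving out 1 library were planned, and tests of other microglia genes, of neighbouring tissue and of other splits for the tissue comparisons were set down before their results were seen, while thinning and the other tests of explanations and splits were chosen only after the result was seen.

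Within groups of 4 libraries, 5 of 42 library measures and 14 of 180 gene levels (30 genes) had a library far from the rest, where chance gives about 1 in 20. The Ttr share was 0.226% in hippocampus LPS 12 h A261, 0.034% in hippocampus LPS 6 h A240, 0.042% in cortex LPS 6 h A241 and 0.033% in cortex LPS 12 h A258, and the ribosomal protein share 1.41% in hippocampus LPS 6 h A242. Hippocampus LPS 24 h A276 stood apart in Ache (57.0 CPM), Etnppl (30.9), Rtp1 (1.53) and S100a8 (2.85), and A274 of that group in Selp (1.16). At 12 h in the hippocampus A259 stood apart in Atp10a (3.82 CPM) and Gfap (601), A261 in Ccl12 (3.51) and A258 in Hif3a (0.364). At 6 h in the hippocampus A242 did so in Ccl12 (1.73) and A243 in Tnf (0.963). In the cortex they were A242 at 6 h in Ccl12 (3.1 CPM), A261 at 12 h in Cxcl10 (7.45) and A274 at 24 h in Clec14a (5.02).

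LPS groups differed between times, by edgeR's test of the difference. The largest differences are given among called genes with a mean of at least 1 log2 CPM, without predicted genes, here and between tissues. Between 6 and 12 h in the hippocampus 370 genes differed, with the largest log2 differences in Iigp1 (1.86), Gbp4 (1.84), Cxcl10 (1.8), Ccl12 (1.76), Scgb3a1 (1.76), Fcrls (1.61), Rtp1 (-2.58), Sult1a1 (-1.32), Pla2g3 (-1.17), Prom1 (-1.06), Wnt9a (-1.01) and Mfsd2a (-1.0). Between 6 and 24 h 1640 differed, led by Gpr34 (2.36), Fcrls (2.27), Ctla2a (2.18), Itgam (2.15), Ly86 (2.07), P2ry12 (1.93), Sult1a1 (-2.68), Rtp1 (-2.49), Plin4 (-2.3), Msr1 (-2.1), Lcn2 (-1.76) and Gpr84 (-1.72). In the cortex 210 differed between 6 and 12 h, led by Scgb3a1 (2.24), Fcrls (2.12), Cxcl10 (1.63), Ecscr (1.43), Ccl12 (1.33), Rsad2 (1.33), Rtp1 (-2.74), Plin4 (-2.59), Cyp1b1 (-1.45), Pla2g3 (-1.36), Mfsd2a (-1.25) and Chil3 (-1.14), and 313 between 6 and 24 h, led by Scgb3a1 (2.27), Fcrls (2.24), Olfml3 (1.5), Slc2a5 (1.46), Capn3 (1.41), Tmem119 (1.34), Rtp1 (-3.08), Plin4 (-2.84), Sult1a1 (-2.1), Il1b (-1.88), Cyp1b1 (-1.42) and Selp (-1.37).

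Responses differed between tissues in 17 genes at 12 h, with the largest hippocampus minus cortex differences in Coch (1.27), Plagl1 (0.93), Ier3 (0.84), Prss23 (0.8), Camk4 (0.7), Fbxo7 (0.57), Klk8 (-1.41), Zap70 (-1.32), Rprm (-0.95), Ramp3 (-0.91), Cyth4 (-0.79) and Epop (-0.69). At 24 h there were 22, led by H2-T23 (1.13), Lrg1 (1.0), Prss23 (0.96), Prr16 (0.83), Fbxo32 (0.7), Rps6ka5 (0.68), Ramp3 (-1.03), Rprm (-0.91), Igsf21 (-0.66), Tubb2b (-0.59), Pfn1 (-0.53) and Dusp14 (-0.52).

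Other library splits into groups of the same sizes were counted, 35 per comparison with LPS. Against saline only the real split gave as many genes. The hippocampus had 884, 2134 and 2309 at 6, 12 and 24 h (highest other 26, 1102 and 579). The cortex had 599, 1219 and 1045 (195, 211 and 149). The same held for 370 and 1640 between hippocampal times (1 and 1) and 313 between 6 and 24 h in the cortex (0). In the fit without the mouse it held for 17 and 22 between tissues (1 and 1). The last 2 counts fell to 8 and 6 with the mouse as a fixed effect and to 2 and 8 without cortex saline A223. With 35 splits mixing the groups, chance is not excluded. It stays open for 210 genes between 6 and 12 h in the cortex, as 2 splits gave as many. The other called 1448 genes and went with the ribosomal protein share, not time. It set LPS 12 h A258, A259 and LPS 6 h A241, A243 (1.41 to 1.54%) against the rest (1.76 to 2.05%). For the tissue difference at 6 h, with 0 genes by edgeR (1031 at an unadjusted p under 0.05; 0 by DESeq2, 8 by limma-voom), all 35 splits had to give as many (highest other 1), so the count says nothing about chance. The 6552 genes between saline tissues (highest other 1) had 10 splits, too few for a share under 0.05.

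Glucocorticoid-responsive genes fell in 8 to 17 of 20 cases after LPS. Scaling and depth are argued against (12, 13 and 13 members called in 3 settings at 6 h in the hippocampus, against 13). So is a single saline library (9 called without A222 or A224, 14 without A226). Fewer endothelial cells and astrocytes are argued against at 24 h, where the medians of their lists (0.11 and -0.09 in the hippocampus, -0.03 and -0.14 in the cortex) lay above those of the pattern (-0.7 and -0.77) by more than the SD of their members (0.61, 0.49, 0.64 and 0.37). At 6 h fewer endothelial cells stay open, with medians of -0.31 and -0.38 (SD 0.47 and 0.46) against -0.5 and -0.51. Collection time is argued against at 6 h, the saline time (8 genes lower in the cortex, 13 in the hippocampus). Later it stays open. CORT intake or timing was not tested.

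Homeostatic microglia genes rose in 13 of 16 cases at 24 h in the hippocampus. Scaling and depth (14, 13 and 12 members called in 3 settings, against 13) and a single saline library (11 called without A222 or A224) are argued against. A list of 16 other microglia genes, drawn up before their response against saline was seen except that a tissue difference of Cyth4 was known, had a median of 0.99, with 14 called higher, such as Aif1 (1.87), Ptprc (2.11) and Spi1 (1.09), against 1.04 for the homeostatic list. More microglia, or RNA per microglial cell, is a candidate explanation. Higher expression per cell of these genes and collection time stay open.

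The ribosomal protein share ran from 1.33 to 2.05% over cortex libraries (median 1.54), and from 1.41 to 2.05% within LPS 6 h, against 1.26 to 1.46% over hippocampal libraries (median 1.35). Transcript length is a candidate explanation: across 16864 genes, which are not independent, the slope on the share correlated with exonic length with rho = -0.507. Neighbouring tissue may contribute, since striatal genes had a median slope of 2.14 (SD 1.13, 13 of 13 above 0, though edgeR called 0), myelin genes 0.3 and meningeal genes -0.37. Whether the mouse sets the share cannot be told apart from chance with 14 mice (r = 0.165, permutation p = 0.566; rho = 0.319, permutation p = 0.266; r = -0.021 without the 2 farthest). No biological explanation was tested, as the variation is within groups.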

How the results depend on the processing

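The mitochondrial and ribosomal covariates, thinning, coding genes alone and the fit without the 3 libraries of high Ttr or mitochondrial share were chosen only after the results were seen. Of 296 counts under alternatives other than leaving out 1 library, 211 were within 1.5 times the count reported, and 85 were not. The cause was not tested except where fewer libraries, more genes tested or a threshold on size makes it plain. Every alternative set beforehand was run.

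Counts below are of genes, with time for LPS against saline unless said. Library totals alone gave 693 lower at 12 h and 737 at 24 h in the hippocampus, and 1158 higher and 316 lower at 12 h and 976 and 267 at 24 h in the cortex. With no filter 678 were lower at 6 h and 894 differed between 6 and 12 h in the hippocampus. DESeq2 gave 318 lower at 6 h in the cortex, 476 and 558 for 12 and 24 h against 6 h there, and 74 and 61 for the tissue difference at 12 and 24 h. DESeq2 size factors gave 10 for the tissue difference at 12 h. Limma-voom gave 862 higher and 710 lower at 6 h in the hippocampus, 685 and 460 at 6 h and 1005 and 762 at 24 h in the cortex, 660 and 2626 for 12 and 24 h against 6 h in the hippocampus, 483 for 24 h against 6 h in the cortex, and 8, 147 and 176 for the tissue difference at 6, 12 and 24 h. Both tissues in 1 fit gave 2.4e+02 lower at 6 h and 721 at 12 h in the hippocampus, 733 higher and 538 lower at 6 h, 875 lower at 12 h and 641 at 24 h in the cortex, and, against 6 h, 152 and 1040 in the hippocampus and 674 and 893 in the cortex.

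The mitochondrial covariate gave 266 lower at 12 h and 217 at 24 h in the cortex, 23 and 37 against 6 h there, and 2 and 10 for the tissue difference at 12 and 24 h. The ribosomal covariate gave 585 for 12 h against 6 h in the hippocampus, 616 and 602 for 12 and 24 h against 6 h in the cortex, and 31 and 81 for the tissue difference. Thinning gave 6 for the tissue difference at 12 h. Without the 3 libraries 174, 518 and 707 were lower at 6, 12 and 24 h in the hippocampus and 127 at 6 h in the cortex, 100 and 108 differed from 6 h in the cortex, and 2 and 4 between tissues. With the mouse as a block the tissue difference had 8 and 6 genes as a fixed effect and 32 and 35 as a random one. The block moved no other count of genes by over 1.5 times.

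Overlaps of genes with an absolute log2 fold change of at least 1 were 178 higher and 28 lower (6 and 12 h), 152 and 24 (6 and 24 h) and 2.4e+02 and 52 (12 and 24 h) in the hippocampus, 160 and 19, 153 and 18, and 2.6e+02 and 56 in the cortex, and 140 and 17, 225 and 41, and 216 and 41 between tissues at 6, 12 and 24 h. Lists called with an estimated correlation were 9, 8 and 7 in the hippocampus and 10, 8 and 8 in the cortex, and fry's direction test called 11 at 6 h in the hippocampus. It turned the direction of the uncalled DNA methylation list at 6 h in the cortex (adjusted p = 0.64).

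Direction turned in genes that were not called. Ache was at 0.00 with library totals (hippocampus 12 h) and thinned (hippocampus 6 h), -0.02 with the ribosomal covariate and -0.07 without A260 (cortex 12 h), -0.03 without A276 and -0.01 without saline A223 (cortex 24 h), 0.01 without saline A224 (cortex 6 h) and 0.01 without A258 (hippocampus 12 h). P2ry12 was at -0.18 with limma-voom and -0.07 with the ribosomal covariate (cortex 12 h), and 0.16 without saline A226 (hippocampus 12 h). Without 1 library Ache ranged from -0.07 to 0.19 and -0.03 to 0.17 in the cortex at 12 and 24 h and from -0.08 to 0.01 in the hippocampus at 12 h, and P2ry12 there from -0.45 to 0.16.

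Leaving out 1 library gave 319 to 498 higher and 165 to 444 lower at 6 h, 723 to 1131 and 654 to 1141 at 12 h, and 864 to 1223 and 661 to 1109 at 24 h in the hippocampus. In the cortex it gave 211 to 455 and 112 to 409, 448 to 647 and 302 to 566, and 427 to 554 and 237 to 394. Against 6 h it gave 172 to 419 and 1132 to 1442 in the hippocampus and 95 to 291 and 108 to 346 in the cortex, between tissues 0 to 0, 2 to 34 and 8 to 40, and between saline tissues 5499 to 6061. Of 3426 values of named genes in these fits 545 lost their call, 3 gained one and 6 changed direction. Of 450 to 492 named values per setting 82 lost it with the mitochondrial covariate, 68 without the 3 libraries, 50 with the ribosomal covariate, 45 with both tissues in 1 fit, 43 with the compared groups alone, 37 thinned, 31 with no filter, 23 with library totals, 14 with limma-voom, 4 with DESeq2, and 3 each with DESeq2 size factors, the stricter filter and coding genes alone. Depth limits genes with few saline counts most, where a ratio's upper bound can exceed the ratio many times over.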

Other observations

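The comparisons here were planned, and the genes were chosen after the data were seen. In the hippocampus 363 genes were higher and 237 lower than saline at all 3 times, and in the cortex 268 and 116. In the hippocampus 4 genes were called in opposite directions at 6 and 24 h, 2 of them lower and then higher, named after their values were seen. They were Tgfbr1, a receptor for transforming growth factor beta (-0.29 ± 0.09, adjusted p = 0.0473, then 0.29 ± 0.08, adjusted p = 0.023), and Luc7l2, a splicing factor gene (-0.21 ± 0.06, adjusted p = 0.0284, then 0.26 ± 0.06, adjusted p = 0.00196).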
